A study of Terfezia claveryi
Helianthemum almeriense and Terfezia claveryi with 9 samples.

How the data were processed

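RNA sequencing of the desert truffle Terfezia claveryi was compared between 3 groups of 3 libraries each, named by the labels as biological replicates. Free-living mycelium was strain T7 kept in shaken liquid culture for 3 months at 23 °C. The other groups were roots of the shrub Helianthemum almeriense, inoculated with truffle spores 3 months before watering was changed, either well watered (soil moisture above 75%) or drought-stressed (soil moisture lowered to 40%, held until shoot water potential was below -2 MPa). RNA came from 100 mg of tissue per sample, per the labels' protocols, and was sequenced as read pairs of 75 bases. Uninoculated plants are mentioned in the labels and were not analysed here.

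Each deposited file lists the same 12765 gene models with 2 columns of counts, which the authors' headers call unique and total gene reads, and with RPKM. FastQC, Bowtie2 2.3.0 and SAMtools 1.7 are named in the submitters' processing notes. The counting program, its filters, its use of strand and the role of each tool are not given in the sources used here. The deposited RPKM values were checked against the counts. RPKM was taken as total gene reads per kilobase, scaled to the total gene reads of the library, and the implied gene length was solved for. For all 11241 gene models with a read in any library, this length was the same whole number in every library where the model had a read, within a relative tolerance of 1e-06. These lengths ran from 156 to 16791 bases with a median of 1132. Of them 61.3% were multiples of 3, so some gene models appear to hold coding sequence alone and others more than that.

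Gene models carry Tercla1 identifiers of the JGI catalogue. The files do not pair them with gene names or product descriptions, and no genome or annotation was used here, so positions and functions are not given. Lists of gene functions that had been fixed as keyword patterns could therefore not be applied, and no gene set test was run.

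Total gene reads were the counts analysed, because the deposited RPKM were built on them. They summed to 15855363 to 31854784 per culture, 869998 to 1635015 per well-watered root library and 3493361 to 5470044 per drought root library. In the root libraries the total is the part of the reads assigned to fungal gene models; the number of reads sequenced per library is not in the files. Whether a count is a read or a read pair is not stated, and reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene with no read was treated as having fewer than 3 counts over the group, which is 0.0386 CPM over the 3 cultures, 0.781 over the 3 well-watered libraries and 0.240 over the 3 drought libraries.

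Each pair of groups was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3: low-count genes were removed with filterByExpr, libraries were scaled by TMM, dispersions were estimated with the robust option, and the quasi-likelihood F test was applied. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Standard errors of log2 fold changes were derived from the F statistic. Levels of single genes are given as CPM, the counts scaled to the total gene reads of the library. A fold against a group without any read was computed from pooled counts against the floor of 3 counts over the group, and a fold against a few reads is given with an exact 95% binomial (Clopper-Pearson) interval. Measures of whole libraries were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1; 15 such tests were made and none has a Benjamini-Hochberg adjusted p below 0.136.

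Groups, tests, alternatives and the rule for named genes were fixed before the data were examined. With no gene names, that rule takes the 2 identifiers with the largest fitted rise and the 2 with the largest fitted fall per comparison, among called genes changed at least 2-fold, with a mean of at least 10 CPM in the higher group and no overlap between replicates. The fitted fold of a gene with 0 or few reads in a group depends on the prior count, so this order is no order of measured folds. The alternatives were DESeq2 1.42.0 size factors, scaling by total counts, other filters on low counts, the DESeq2 Wald test, limma-voom (limma 3.58.1), a joint fit of all 9 libraries, thinning to 869998 reads per library, stricter thresholds, the replicate number as a block, removal of the most abundant genes, and leaving out each library. Unique gene reads were added as an alternative after the files had been seen.

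The edgeR step was tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes per comparison. For drought against well-watered roots (8029 genes) 5.97% of 2-fold, 59.7% of 4-fold and 95.5% of 8-fold changes were called, with 7 false calls among 114. For well-watered roots against cultures (8919 genes) the shares were 23.9%, 71.6% and 92.4%, with 12 false calls among 137. For drought roots against cultures (9001 genes) they were 14.9%, 59.7% and 74.2%, with 10 false calls among 109. Far fewer genes were changed in the simulation than were called in the data, so these shares need not hold for the real fits. As a check for a library deposited more than once, the counts of replicates were compared: their chi-square per degree of freedom was between 4.09 and 73.6, where the same library would give about 1 or less. This says nothing more about the spread between replicates.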

Results

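The fungal transcriptome of Terfezia claveryi was measured in cultured mycelium, in well-watered mycorrhizal roots and in drought-stressed mycorrhizal roots, with 3 libraries per group. Cultures held 25902487 ± 8750490 total gene reads (SD, n = 3). Well-watered roots held 1279646 ± 385386 and drought roots 4169062 ± 1126965 fungal reads (SD, n = 3 each). Fungal totals were thus 20.2-fold lower in well-watered roots and 6.21-fold lower in drought roots than in cultures, and 3.26-fold higher in drought than in well-watered roots. No totals overlapped between groups, and each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Depth and group are therefore tied in every comparison.

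Libraries of a group resembled each other more than those of other groups. Across 8690 gene models, Pearson correlations of log2 CPM were 0.980 to 0.994 among cultures, 0.837 to 0.881 among well-watered roots and 0.832 to 0.933 among drought roots. Between cultures and roots they were 0.597 to 0.661 for well-watered and 0.619 to 0.656 for drought roots. Between the watering regimes they were 0.618 to 0.781. These correlations are across genes, which are not independent replicates. The first principal component separated cultures from roots, and the second separated the watering regimes. Drought replicate 2 lay farthest along the second component on the drought side.

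**Figure D1:**
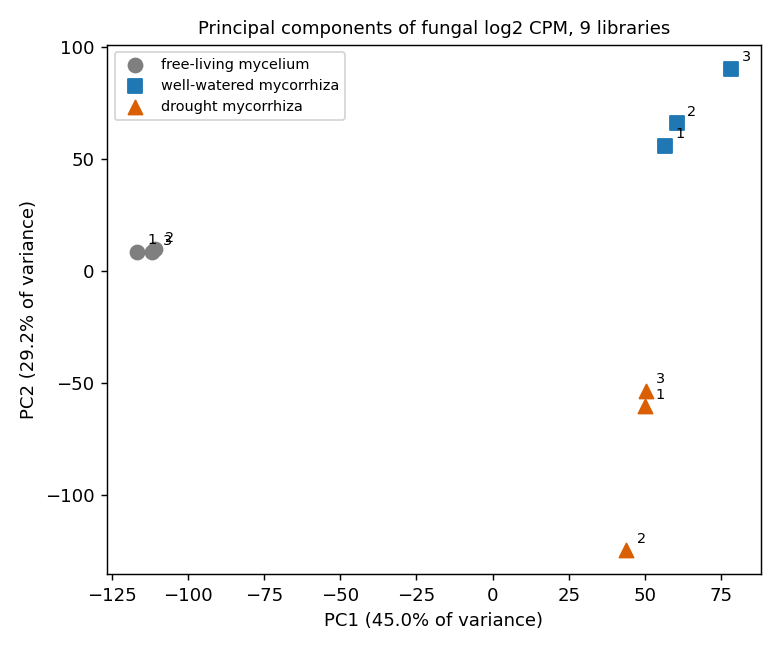
Principal components of log2 CPM over 8690 gene models (axes: component scores, with the share of variance on each axis); each point is a library, numbered by replicate, and colour and shape give the group. Cultures stand apart from roots on the first component, and well-watered and drought roots lie on opposite sides of the second, with drought replicate 2 at its extreme.

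The comparison of drought with well-watered roots asked which fungal transcripts in the mycorrhiza respond when the host plant is short of water. Of 8029 gene models tested, 765 rose and 822 fell under drought (edgeR quasi-likelihood test, adjusted p under 0.05). By the fitted fold change, 129 genes were at least 16-fold higher and 67 at least 16-fold lower. The 129 genes took 0.111 ± 0.0129% of fungal reads in well-watered roots and 8.87 ± 0.554% in drought roots (SD, n = 3 each). The 67 genes took 3.54 ± 0.779% in well-watered roots and 0.165 ± 0.0292% under drought. These shares describe genes selected on the same libraries.

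A set of 24 gene models had no read in any well-watered library and at least 10 reads in every drought library, at a median of 11.7 CPM under drought (range of gene means 3.09 to 1751). Only 3 gene models showed the reverse, at 15.6 to 276 CPM in well-watered roots. The floor of 3 counts was 0.781 CPM over the well-watered group and 0.240 CPM over the deeper drought group, so the numbers 24 and 3 do not rest on equal depth. The 24 became 46, 62, 49 and 41 without well-watered replicates 1 and 2 and drought replicates 2 and 3, and the 3 became 5, 8, 5 and 6 without well-watered replicate 3 and drought replicates 1, 2 and 3. Which fungal genotypes grew from the spores in each plant is not given in the sources used here, so the absence of a gene from some of them was not ruled out for the gene models without reads in well-watered or in drought roots. The largest fitted rise was that of jgi|Tercla1|1084750| (573 bases), which had 0 reads in well-watered roots and 1751 ± 470 CPM in drought roots (SD, n = 3), at least 2183-fold higher (edgeR adjusted p = 2.00e-05). The bound was 1424 without well-watered replicate 1 and 1253 without well-watered replicate 2. It was found at 1.71 ± 0.916 CPM in cultures. jgi|Tercla1|1084858| (198 bases) went from 0 reads to 559 ± 403 CPM, at least 665-fold higher (edgeR adjusted p = 0.000177), and was at 3.73 ± 0.833 in cultures. Drought replicate 2 held 1023 CPM of it, and without that library the mean was 327 CPM and the rise at least 410-fold; without well-watered replicates 1 and 2 the bound was 434 and 382. The largest fitted fall was that of jgi|Tercla1|1274210| (2796 bases), from 276 ± 113 CPM to 0 reads, at least 1162-fold lower under drought (edgeR adjusted p = 2.24e-05), or at least 654-fold without drought replicate 1. Cultures held it at 118 ± 33.7 CPM. jgi|Tercla1|927125| (1383 bases) stood at 384 ± 177 CPM in well-watered roots, 389 ± 130 in cultures and 0.443 ± 0.615 in drought roots. Its drought count was 5 reads against 1498, a 976-fold pooled ratio (95% interval 417 to 3011), with an edgeR adjusted p of 2.00e-05. Of the 5 reads 4 were in drought replicate 3, without which the ratio was 3517 (95% interval 630 to 139018).

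The number of changed genes under drought moved when single libraries were left out, which also leaves fewer libraries for the test. It was 1747, 874 and 879 without well-watered replicates 1, 2 and 3, and 1074, 1630 and 1166 without drought replicates 1, 2 and 3. Genes lower numbered 536 without drought replicate 1. A joint fit of all 9 libraries called 2420 changed genes.

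The comparison of well-watered roots with cultures asked which fungal transcripts differ between symbiosis and free growth. Of 8919 gene models tested, 2176 were higher and 2183 lower in the roots (edgeR quasi-likelihood test, adjusted p under 0.05), 48.9% of those tested. Changes of at least 2-fold were found for 1736 higher and 1685 lower genes. By the fitted fold change, 370 genes were at least 16-fold higher in the roots and took 7.59 ± 0.616% of fungal reads there, against 0.220 ± 0.00629% in cultures (SD, n = 3 each, genes selected on the same libraries). On the other side 260 genes were at least 16-fold lower and took 2.24 ± 0.0309% of reads in cultures and 0.0547 ± 0.00760% in well-watered roots, but their number was 144, 138 and 140 without culture replicates 1, 2 and 3 and 102 after thinning to one depth. The largest fitted rises were those of jgi|Tercla1|1176117| (3028 bases) and jgi|Tercla1|1176131| (2081 bases). The former had 0 reads in cultures and 1261 ± 720 CPM in well-watered roots (SD, n = 3), at least 33251-fold higher (edgeR adjusted p = 2.72e-05). The bound was 22097 without well-watered replicate 1, 19620 without culture replicate 2 and 20415 without culture replicate 3. The latter had 1 read in cultures and 1583 ± 236 CPM in well-watered roots (edgeR adjusted p = 1.87e-06), a ratio of 124387 with a 95% interval from 22317 to 4913797. Without culture replicate 1, which held that read, the rise was at least 33002-fold, and the ratio was 73397 (interval 13168 to 2899474) without culture replicate 2 and 76370 (13702 to 3016930) without culture replicate 3. In drought roots these genes stood at 29.7 ± 8.05 and 82.6 ± 12.6 CPM. Their presence in the genome of strain T7 was not shown by 0 or 1 read, so these folds may reflect a gene missing from the cultured strain and not a change in expression.

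The largest fitted falls from culture to well-watered root were those of jgi|Tercla1|1190283| (1088 bases) and jgi|Tercla1|1281898| (378 bases). The former was at 226 ± 110 CPM in cultures (SD, n = 3) and had 0 reads in well-watered roots, at least 321-fold lower (edgeR adjusted p = 0.000401). The latter was at 86.5 ± 23.5 CPM in cultures with 0 reads in well-watered roots, at least 104-fold lower (edgeR adjusted p = 0.000115). Without well-watered replicates 1 and 2 the bounds were 210 and 184 for the former and 68.18 and 59.99 for the latter. With 0 reads in the roots, either gene may be missing from the fungi that grew from spores. All reads of jgi|Tercla1|1281898| were shared with other gene models, so its level is uncertain. Cultures grown from strain T7 and roots inoculated with spores also differed in fungal source material, growth conditions and depth, and genes lower numbered 1335 without culture replicate 2 and 1342 without culture replicate 3.

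Drought roots were compared with cultures in the same way. Of 9001 gene models tested, 1926 were higher and 1958 lower in drought roots (edgeR quasi-likelihood test, adjusted p under 0.05), 43.2% of those tested, and 1506 higher and 1427 lower genes changed at least 2-fold. By the fitted fold change, 326 genes at least 16-fold higher took 12.2 ± 1.62% of fungal reads in drought roots and 0.208 ± 0.0271% in cultures (SD, n = 3 each, genes selected on the same libraries). The 290 genes at least 16-fold lower took 3.79 ± 0.134% in cultures and 0.119 ± 0.00975% in drought roots, and numbered 442 without drought replicate 3 and 116 after thinning. jgi|Tercla1|1273504| (2136 bases) had 1 read in cultures, 178 ± 75.3 CPM in well-watered roots and 1813 ± 196 in drought roots (SD, n = 3). The ratio of drought roots to cultures was 139557 with a 95% interval from 25045 to 5512448 (edgeR adjusted p = 7.79e-06). Without culture replicate 1, which held that read, the rise was at least 37027-fold, and the ratio was 82348 (interval 14778 to 3252718) without culture replicate 2 and 85684 (15377 to 3384484) without culture replicate 3. As above, 1 read did not show that the gene is present in strain T7. jgi|Tercla1|1161677| (1497 bases) was at 12646 ± 10383 CPM in drought roots against 0.202 ± 0.267 in cultures (edgeR adjusted p = 0.000792), and at 4.51 ± 6.16 in well-watered roots. Well-watered replicate 2 held 19 of the 21 reads, and without it the mean was 0.950 CPM. Of its 11 culture reads 8 were in culture replicate 1, without which the log2 fold change of drought roots against cultures was 17.76, against 16.30 with all libraries, 15.51 without culture replicate 2 and 16.89 without drought replicate 2. Its drought libraries ranged from 691 in replicate 2 to 19412 CPM. Limma-voom gave it a log2 fold change of 16.04 ± 7.32 (SE) and an adjusted p of 0.104. The adjusted p of the other alternatives (edgeR or DESeq2) ran from 1.43e-18 to 0.00684.

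The largest fitted falls from culture to drought root were again that of jgi|Tercla1|1190283|, with 0 reads in drought roots and at least 1046-fold lower (edgeR adjusted p = 0.000699; at least 589-fold without drought replicate 1), and that of jgi|Tercla1|1147375| (675 bases). The latter stood at 207 ± 31.4 CPM in cultures (SD, n = 3) and had 0 reads in drought roots, at least 838-fold lower (edgeR adjusted p = 5.92e-05), or at least 472-fold without drought replicate 1. It had 3 reads in well-watered roots, all in replicate 2. Of its reads 98.5% were shared with other gene models, so its level and fold bounds are uncertain. On unique gene reads its log2 fold change of drought roots against cultures was -8.55 ± 1.46 (SE, edgeR adjusted p = 0.00735), against -14.60 in the main fit. For both genes, absence from the fungi that grew from spores in the drought roots was not ruled out. The number of changed genes against cultures was 2516 without culture replicate 2 and 2494 without culture replicate 3, and genes lower numbered 2994 without drought replicate 2.

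**Figure D2:**
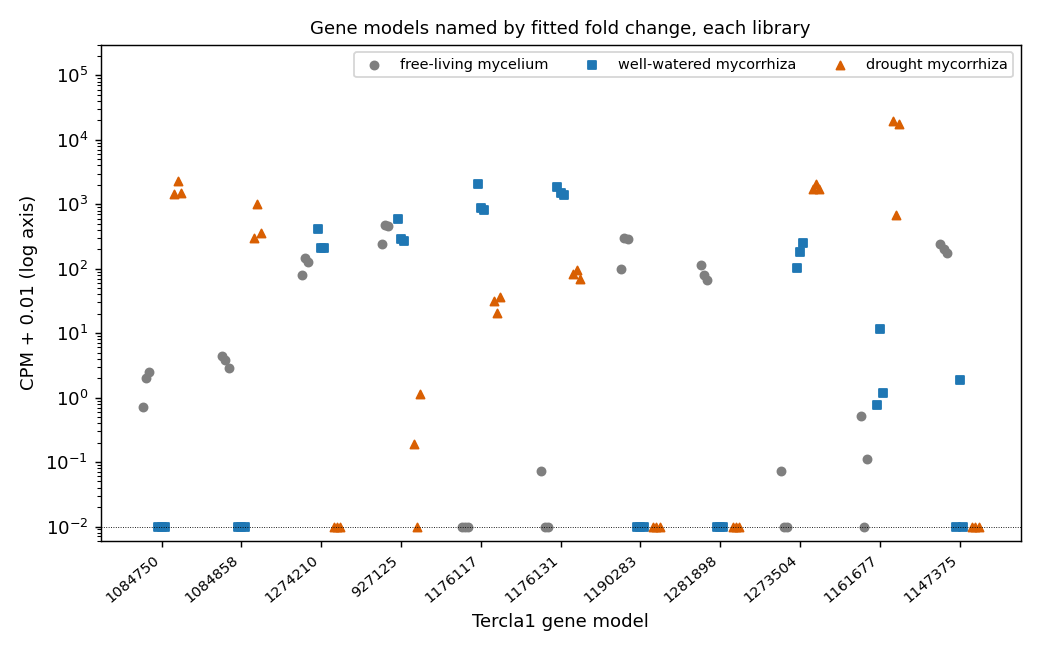
CPM (plus 0.01, log axis) of the 11 gene models named for the largest fitted rises and falls; each point is a library, colour and shape give the group, and points on the dotted line had 0 reads. Models 1084750 and 1084858 have 0 reads in every well-watered library and at least 295 CPM in every drought library, and drought replicate 2 lies below the other drought libraries for model 1161677.

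The lists against cultures were then set beside each other to find the changes shared by both root groups. Of 8784 gene models tested in both, 1053 were higher and 1145 lower in both root groups. Independent lists of these sizes would share 428 and 484. Both comparisons use the same cultures. In 20 simulations, unchanged root groups were drawn around the means of the real cultures and set against those cultures. At most 0 genes were called in both, the mean correlation of log2 fold changes was 0.0603 and their mean covariance 0.0256. The observed correlation was 0.720 and the observed covariance 3.71. The simulated means were those of the same cultures, which leaves out the error of the cultures. These simulations therefore cannot measure what sharing the cultures adds. The 3 cultures were not divided between the comparisons, so part of the excess may come from the shared controls. Genes changed the same way numbered 1464, 1325 and 1303 without culture replicates 1, 2 and 3.

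Most genes raised in both root groups did not pass the test between watering regimes, but neither did most of all tested genes. Of all 8029 gene models tested between the regimes, 19.8% passed. Not passing does not show a lack of change, since 5.97% of simulated 2-fold changes were called in that comparison. Of the 1053, 141 fell and 76 rose under drought, 833 did not pass and 3 were not tested. Of the 1145 lower in both, 51 fell further and 32 rose under drought, 848 did not pass and 214 were not tested. A further 921 genes were higher than in cultures in well-watered roots without passing in drought roots, and 306 of them fell under drought. Conversely, 651 genes were higher in drought roots without passing in well-watered roots, and 256 of them rose under drought. Opposite directions were found for 207 genes: 117 were lower in well-watered and higher in drought roots than in cultures, and 90 the reverse. All 207 also passed the direct test between the watering regimes, which uses the same root libraries by which they were selected and is no independent evidence. Independent lists would give 910 genes with opposite directions. The 207 became 119, 91 and 93 without culture replicates 1, 2 and 3, and 328 without well-watered replicate 1.

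**Figure D3:**
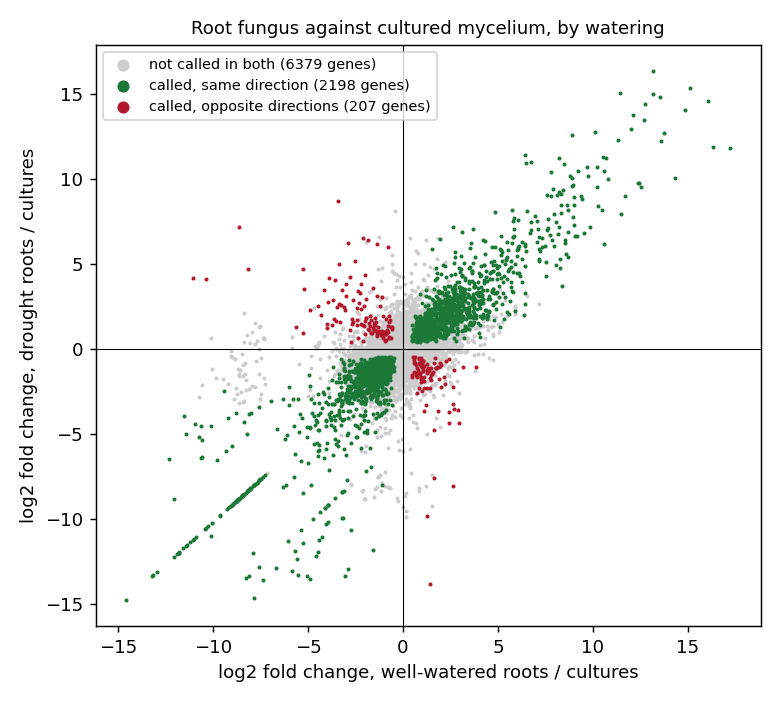
log2 fold change of each of 8784 gene models in well-watered roots (horizontal axis) and in drought roots (vertical axis), each against cultures; colour separates the 2198 genes called in the same direction, the 207 called in opposite directions and the remaining genes. Genes with 0 reads in every root library form the straight line at the lower left, where the fitted fold depends on the prior count.

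Some gene models were read on 1 side of the change from culture to root and not on the other. A group of 15 gene models had 0 reads in every culture, below a floor of 0.0386 CPM over the group, and at least 10 reads in each of the 6 root libraries, at a median of 87.7 CPM (range of gene means 16.7 to 646). In the other direction, 24 gene models had at least 100 reads in every culture and 0 in every root library, below a floor of 0.184 CPM over the 6, at a median of 23.1 CPM in cultures (range 4.80 to 226), and 42 gene models did so without culture replicate 1. Cultures were strain T7 and roots were inoculated with spores, so either group may hold genes that are missing from the fungus on the side without reads, and 0 reads there do not separate a silent gene from a missing one.

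The share of reads in the 10 most abundant gene models was 11.9 ± 0.287% in cultures, 10.6 ± 0.355% in well-watered roots and 8.65 ± 0.903% in drought roots (SD, n = 3 each). Each pair of groups differed without overlap, with an exact two-sided permutation p of 0.1, the smallest possible. For the 50 most abundant models the order of cultures and well-watered roots turned, at 20.6 ± 0.491% and 21.5 ± 0.676%. Of the 10 most abundant models of each group, cultures and well-watered roots shared 6, cultures and drought roots 2, and well-watered and drought roots 2.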

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

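In well-watered roots 3.08 ± 0.0729% of total gene reads (SD, n = 3) were not unique to a gene model, above every culture (2.73 ± 0.0684%), while drought roots lay below every culture at 2.40 ± 0.0408%. The exact two-sided permutation p was 0.1 for each pair, the smallest possible. These shared reads were not used apart from the totals, and no biological explanation was tested.

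Against cultures, 207 gene models changed in opposite directions in the 2 root groups. All 207 were called in the direct edgeR test between the regimes, which uses the same root libraries by which they were selected and adds no independent evidence. Among the genes named for their change against cultures, jgi|Tercla1|1176117| was lower in drought than in well-watered roots by a log2 fold change of -5.52 ± 0.476 (SE, edgeR adjusted p = 5.75e-05) and jgi|Tercla1|1176131| by -4.40 ± 0.323 (edgeR adjusted p = 2.34e-05). jgi|Tercla1|1273504| was higher under drought by 3.18 ± 0.407 (edgeR adjusted p = 0.000569) and jgi|Tercla1|1161677| by 11.13 ± 1.58 (edgeR adjusted p = 0.00144), or by 13.62 ± 2.02 (edgeR adjusted p = 0.00438) without well-watered replicate 2, which held 19 of the 21 reads of that group.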

How the results depend on the processing

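Unique gene reads were an alternative chosen after the values were seen. No gene called in any of the 3 comparisons was called in the reverse direction under any alternative. At an adjusted p under 0.01 the numbers changed, higher and lower were 785, 397 and 388 for drought against well-watered roots, 2318, 1200 and 1118 for drought roots against cultures, and 2813, 1562 and 1251 for well-watered roots against cultures; 1198 genes changed the same way in both root groups and 77 in opposite directions. A joint fit of all 9 libraries called 2420 genes between the watering regimes, 1333 of them lower under drought. With a fold minimum of 2, 129 genes had opposite directions. Genes at least 16-fold lower than in cultures numbered 260 in well-watered roots, 171 at an adjusted p under 0.01, 145 with limma-voom, 102 after thinning and 138 to 144 without a culture, and 290 in drought roots, 116 after thinning and 442 without drought replicate 3. The well-watered minus culture difference in read share turned from -1.23 to 0.929 percentage points for the 50 most abundant genes. Leaving out each library gave 874 to 1747 changed genes between the watering regimes (448 to 831 higher, 424 to 916 lower), 2494 to 5701 between drought roots and cultures (1246 to 2707 higher, 1248 to 2994 lower), 2945 to 5317 between well-watered roots and cultures (1603 to 2485 higher, 1335 to 2832 lower), 1303 to 2931 genes changed the same way and 91 to 328 in opposite directions. The cause was not tested for any of these. Scaling by total counts moved the median log2 fold change from 0.08 to 0.22 between the watering regimes and from -0.11 to -0.31 between well-watered roots and cultures, and the share of calls that were higher from 48.2% to 57.8% and from 49.9% to 40.6%. Of 202 separate refits of the 12 named changes 201 kept their direction and call. These changes were selected as the largest fitted ones on the same libraries, so keeping the call in a refit is no independent evidence. Limma-voom gave jgi|Tercla1|1161677| against cultures an adjusted p of 0.104, with a log2 fold change of 16.04 ± 7.32 (SE) against 16.30 in the main fit. The refits do not cover this gene without the most abundant genes, which removed it. Nor do they cover jgi|Tercla1|1281898| on unique gene reads, since all its reads were shared, so its change was not tested there. With the replicate block, 1335, 3854 and 3025 genes were called for drought against well-watered roots, well-watered roots against cultures and drought roots against cultures; libraries with the same number shared only the number, their deviations correlating between -0.0837 and 0.0975 over 9 pairs, and 5 of 18 best matches were to the same number. Fewer genes were called against cultures at one depth. With all libraries thinned to 869998 reads, 3271 genes were called for well-watered and 3015 for drought roots. Of the original calls 728 and 569 were then no longer tested. Alternatives for gene lists were not run, since no gene names were used.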

Other observations

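The tests for a mixed or swapped library, for the depth of drought replicate 2 and for reads of the host plant were chosen after the results were seen. Fewer gene models held 50% of the fungal reads in well-watered roots than elsewhere. Their number was 459 ± 51.4 there (SD, n = 3), against 574 ± 12.5 in cultures and 600 ± 33.9 in drought roots. It did not overlap between well-watered roots and either other group (exact two-sided permutation p = 0.1 each, the smallest possible). The most abundant model in cultures took 4.34 ± 0.188% of reads there, 1.05 ± 0.170% in well-watered roots and 1.83 ± 0.762% in drought roots. That model ranked 4 in well-watered roots and was also the most abundant in drought roots. The most abundant model in well-watered roots took 2.07 ± 0.589% there, 0.798 ± 0.188% in cultures and 0.320 ± 0.0535% under drought, where it ranked 20. At 869998 reads per library, 8838 to 8985 gene models had a read in cultures, 8538 to 8860 in well-watered roots and 8218 to 8909 in drought roots, the lowest being drought replicate 2.

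Drought replicate 2 stood apart from the other drought libraries. RNA of a well-watered root in that library, or a swap with one, would pull it towards the well-watered group, but over the 1630 genes called without it, it showed a median 1.09 times the change of the other drought libraries (quartiles 0.771 and 1.43), against 0.907 for replicate 1 and 0.867 for replicate 3 in the same test. Depth is argued against as well, since replicate 2 held 1.01 times the reads of replicate 3 (3543782 against 3493361), while over 8283 genes replicate 1 correlated at 0.950 with replicate 3 and at 0.840 with replicate 2. A further advanced drought response in that plant is a hypothesis that stays open: across 8029 genes the drought effect of replicate 1 correlated with replicate 2 minus replicate 3 at a Spearman rho of 0.175, and the arrangement with replicates 1 and 3 exchanged gave 0.102, between the bounds set for and against it.

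Drought and well-watered libraries differed 3.26-fold in depth. If the depth difference made the calls, thinning every library to one total would remove most of them, but 1608 genes were called after thinning, against 1587 before, and 1445 of the 1587 kept their call and direction. Biological and other differences between the plants of the 2 groups stay open.

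Genes higher in both root groups than in cultures might include models that collect reads of the host plant. Such reads would weigh more where fungal reads are few, so that, if root libraries had like totals, these models would fall from well-watered to drought roots by about the 3.26-fold difference in fungal depth. The 1050 genes tested differed from the other genes by a median log2 fold change of -0.160 (95% bootstrap interval across genes -0.229 to -0.0960). That interval treats genes as independent and does not measure the spread between libraries. The set was also selected on the same root libraries. The number of reads sequenced per library is not in the files, so a part played by plant reads stays open, and it may be larger for single genes than for the set.

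For each of the 3 comparisons, 1 of the 10 splits of the 6 libraries, the real one, called as many genes, with 1587, 4359 and 3884 genes against at most 0 in any other split; 10 splits cannot give a share under 0.05. For the genes changed the same way in both root groups, 1 of 100 splits of the 9 libraries, the real one, gave 2198 genes, and the highest of the others gave 1541. That split and the next, with 1260, kept the cultures together and mixed the root libraries. The share of 1 in 100 therefore bears only on the separation of cultures from roots. With the cultures kept together the 6 root libraries can be divided in 10 ways, too few for a share under 0.05. In both kinds of split, mixing unlike libraries widens the spread within a group, and 94 of the 100 splits gave no gene. The size of the gap to the real count is therefore no measure of support.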
